A study of Homo sapiens with 2 samples.

How the data were processed

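RNA of HEK293T cells was sequenced in 2 libraries, 1 labelled control siRNA and 1 labelled SRα siRNA. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit. The deposited values are whole-number read counts per Ensembl gene ID, with no normalization. Per the submitters' processing notes, cutadapt and STAR 2.5.2b were used and the genome build was hg19. The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Each file ends with 5 summary lines whose names have the style of htseq-count, which named no gene and were kept out of library sizes.

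In the control siRNA library, 10840225 of 13615728 entries (79.6%) were alignments that were not unique, and in the SRα siRNA library 14433595 of 18865195 (76.5%). A read aligned to several places may be entered more than once in such a line, so these are shares of alignments, not of reads. Of uniquely aligned reads, 88.1% and 87.9% were assigned to genes, 7.23% and 7.49% lay in no gene, 4.67% and 4.58% matched several genes and 0 were below the quality limit. Since only unique alignments were counted, genes with near-identical copies lose reads, and because use of strand is unknown, overlapping and antisense genes cannot be told apart. The median measured gene had 58 reads in the control siRNA library and 88 in the SRα siRNA library, and at that depth the 95% counting interval reaches 1.41-fold down and 1.42-fold up from the measured ratio.

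Both files list the same 57820 gene IDs. Symbols came from a table of gene names for 51996 IDs and from GENCODE 29 for 342, and 5482 had none, holding 1.42% and 1.40% of gene reads. GENCODE 29 was used by gene ID alone, for gene type, GC content, exonic length and coding sequence. No coordinates are given, because an annotation of hg19 was not used here.

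Libraries were scaled by edgeR's TMM factors (edgeR 4.0.16, R 4.3.3). The effective library sizes were 2476276 and 3847820. A log2 ratio is that of the CPM of the SRα siRNA library over the control siRNA library, with a prior count of 0.5 scaled to depth. Its 95% interval is the exact (Clopper-Pearson) binomial interval of the 2 counts given their sum. Without unique molecular identifiers, reads are not independent molecules, so intervals cover counting error only. Genes with a mean of at least 1 CPM over both libraries were called measured. With 1 library per group no test between conditions is possible and no p-value is given. Genes were counted by a fixed size of 2-fold. Counting error was simulated in 100 pairs of libraries with Poisson counts around equal levels.

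The gene lists (38 lists, 1047 genes), the choices of scaling, filter and prior, the rule for named genes and most alternatives were fixed before the data were examined. The rule names SRPRA, the 12 highest and 12 lowest ratios among genes with a mean of at least 5 CPM, up to 2 highest and 2 lowest members of a list, and SRPRB, SRP54, NCBP1, EIF4E, UPF1 and CTIF. Some genes that the rule takes are not reported here. A list's median was ranked among 10000 random lists drawn from measured genes in 20 bins of mean CPM, and called low or high outside percentiles 2.5 and 97.5. For lists matched on GC or length as well, 10 bins of each property were crossed. A list with fewer than 3 measured members was not ranked. GC and length were known for 98.8% of measured genes and for every measured list member. Trends were removed with splines of 4, 5 and 4 degrees of freedom on expression, GC and length. Matching on GC, removal of trends, restriction to protein-coding genes and the naming of genes of at least 50 CPM were added after the values had been seen.

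Hydrophobic segments were predicted in the longest coding sequence of each gene with the Kyte-Doolittle scale, as windows of 19 residues with a mean of at least 1.6 or, in the first 25 residues, windows of 12 residues with a mean of at least 2.0. Segments in the last 50 residues were classed as C-terminal. Alternatives were DESeq2 1.42.0 size factors, library totals, upper quartile factors, no filter, a higher filter, a prior count of 2, thinning to equal totals, totals without mitochondrially encoded genes and the 10 most-read genes, other matching, and list means. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

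The procedure was tested on counts simulated for this comparison over all 57820 gene IDs, with 200 genes set apart by known folds. The interval held the true value for 94.0% of genes set 2-fold higher, 90.0% set 2-fold lower, 96.0% set 1.5-fold higher, 96.0% set 1.5-fold lower and 96.1% of genes left equal. Of simulated lists of 30 genes, over 12756 measured genes, 10 of 10 lists lower by 0.15 (log2) and 7 of 210 unshifted lists lay outside the central 95%. Most lists called low in the results differed from random lists by less than 0.15. Simulated counts otherwise varied by counting error alone, so the check does not cover smaller shifts or lists whose genes vary together.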

Results

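Messenger RNA sequencing was done on HEK293T cells, an established human embryonic kidney line, in 1 library from cells given a control siRNA and 1 library from cells given an siRNA against SRα. SRα is the alpha subunit of the receptor for the signal recognition particle (SRP), encoded by SRPRA. The receptor sits in the membrane of the endoplasmic reticulum (ER) and takes over ribosomes whose growing protein carries a signal sequence bound by SRP. The control siRNA library held 2445200 reads assigned to genes and the SRα siRNA library held 3896721, with at least 1 read in 16001 and 17081 genes. The comparison asks how message levels differ between cells with and without depletion of SRα. Ribosome profiling, which the design also describes, was not analysed here. There were no replicates, so the difference between the libraries has no replicate check, no test was made, and every interval given covers counting error only.

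The message of the depleted gene was lower in the SRα siRNA library. SRPRA stood at 0.570 times its control level, the lowest ratio among the 4007 genes with a mean of at least 50 CPM (the read count scaled to library size), a limit set after the values were seen. At the limit of 5 CPM set beforehand, it ranked 100 from the lowest of 10104 genes. Few other well-read genes lay far apart. Of these 4007 genes, 2 were at least 2-fold higher in the SRα siRNA library, neither of them protein-coding, and 0 were at least 2-fold lower. Messages for signalling receptors, GPI-anchored and secreted proteins, ER chaperones, N-glycan assembly and the EMC and GET pathways were lower by small amounts as groups. Of these groups, only signalling receptors stayed low in every alternative setting. The translocon and signal peptidase list lay within the random range when matched on expression. It was low once trends with GC and length were removed (percentile 0.245) and with list means (1.585). Of 12 lists of secretory and membrane genes, grouped so after their values were seen, 8 lay below random lists matched on expression, against 3 of 24 other lists. The 12 are the 8 low lists (signalling receptors, GPI-anchored proteins, matrix and secreted proteins, solute carriers, lysosome, EMC and GET, N-glycan assembly and ER chaperones) and those of the translocon and signal peptidase, ER-associated degradation, COPII and COPI transport, and integrins. The tally was 6 against 2 with GC content matched as well, and 2 against 0 with no matching.

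SRPRA (ENSG00000182934.7) had 507 reads in the control siRNA library and 449 in the deeper SRα siRNA library, or 205 and 117 CPM. The log2 ratio was -0.81 (95% counting interval -0.998 to -0.62), a ratio of 0.570 (0.501 to 0.648). The other receptor subunit, SRPRB, which anchors SRα in the membrane, had a log2 ratio of -0.07 (-0.23 to 0.09), and SRP54, the SRP protein that binds signal sequences, had 0.03 (-0.18 to 0.25). The cap-binding protein NCBP1 (CBP80) had 0.03 (-0.15 to 0.21), the cytoplasmic cap-binding protein EIF4E had -0.11 (-0.89 to 0.69) from 25 and 36 reads, the initiation factor CTIF had -0.04 (-0.72 to 0.67), and UPF1, the helicase of nonsense-mediated decay (NMD), had -0.04 (-0.22 to 0.14). No difference was detectable for these 6 genes at this depth.

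Over the 12747 genes with a mean of at least 1 CPM, 274 were at least 2-fold higher and 328 at least 2-fold lower in the SRα siRNA library, and the standard deviation of the log2 ratios was 0.480. Pairs of libraries simulated to differ by counting error alone gave 243 to 328 genes higher and 247 to 322 lower, with standard deviations of 0.428 to 0.465. The number of higher genes thus lay within what the depth alone gives, and the number of lower genes and the standard deviation were above the highest of 100 simulated pairs by small margins. Among genes of at least 50 CPM the spread was 0.152, against 0.111 to 0.119 in 100 simulated pairs. In that range 7 genes were at least 1.5-fold higher and 2 at least 1.5-fold lower, against averages of 0.13 and 0.12 in the simulated pairs.

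**Figure D1:**
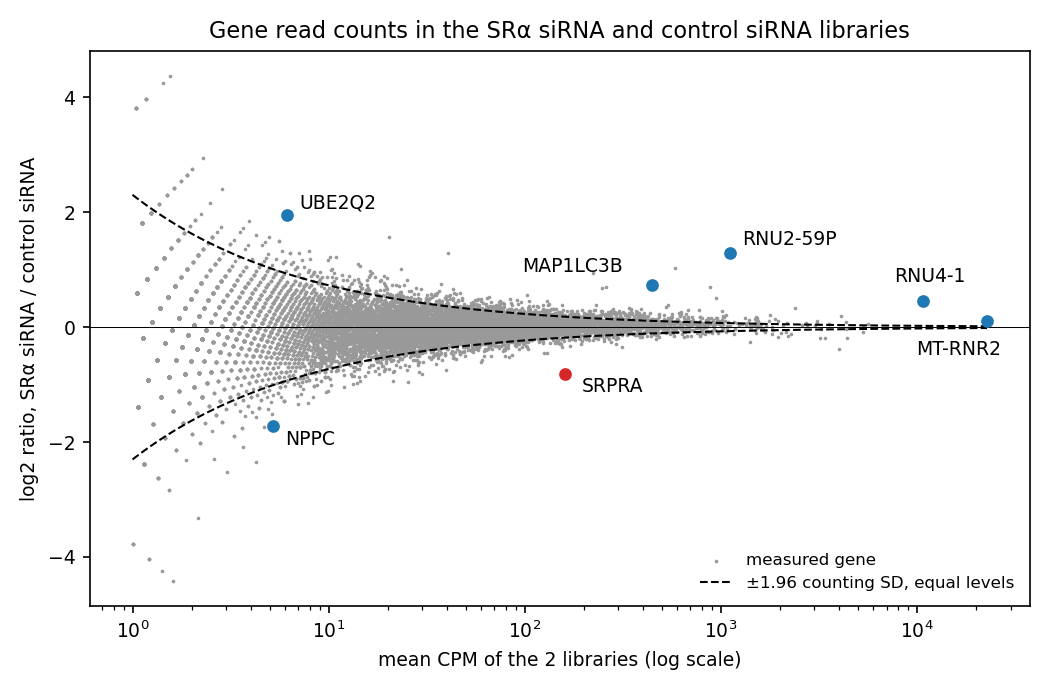
Log2 ratio of each measured gene, SRα siRNA over control siRNA, against its mean CPM in the 2 libraries on a log axis, with dashed lines at the 95% range that counting error gives around equal levels. SRPRA, at -0.81, lies below the lines, and RNU2-59P, at 1.29, lies above them.

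Among genes of at least 5 CPM, the 12 highest ratios were led by UBE2Q2, a ubiquitin-conjugating enzyme, with 6 and 38 reads and a log2 ratio of 1.959 (0.77 to 3.56), and by the unnamed gene ENSG00000234699 at 1.58 (0.96 to 2.28). They included an entry of 7SK, the small nuclear RNA that restrains transcription elongation, and SCG3, a secretory granule protein, both at 1.51 (0.35 to 2.98). HES7, a repressor downstream of Notch, had 58 and 221 reads and a ratio of 1.29 (0.87 to 1.74). ARL6IP1, a protein that shapes ER membrane, had 1.29. The zinc finger genes ZNF829, ZNF804A, ZNF490 and ZNF189 lay between 1.23 and 1.33, and RNU2-59P, a copy of the spliceosomal U2 RNA, was at 1.29 (1.21 to 1.37).

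The 12 lowest ratios came from genes with 18 to 29 reads in the control siRNA library and 9 to 19 in the SRα siRNA library. NPPC, the precursor of C-type natriuretic peptide, had -1.72 (-3.11 to -0.59), CITED4, a transcriptional coactivator, had -1.51 (-2.83 to -0.39), the orphan receptor GPR27 had -1.34 (-2.40 to -0.39) and the reticulon RTN2 had -1.32 (-2.32 to -0.44). EVI5L, PLEKHG2, BARX1, NUDT14, KCNJ11, CAMTA2, TRIM62 and the unnamed ENSG00000251806.1 lay between -1.3 and -1.19. These genes were picked as the extremes of 10104, and their intervals take no account of that choice.

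A second rule, the 15 highest and 15 lowest genes of at least 50 CPM, was added after the values had been seen. RNU2-59P again had the highest ratio, followed by the unnamed ENSG00000260464 at 1.02 (0.92 to 1.13). MAP1LC3B, the LC3 protein of autophagosomes, had 332 and 554 CPM and a ratio of 0.74 (0.62 to 0.86). The translation elongation factor EEF1A1 had 0.68 (0.52 to 0.84), the U4 RNA gene RNU4-2 had 0.69 (0.61 to 0.77), ZNF773 had 0.70 (0.54 to 0.85), and TTK, a kinase of the spindle checkpoint, had 0.55 (0.31 to 0.80). TOX4, RPS3P3, BEX1, CHCHD1 and GTF3A lay between 0.48 and 0.50. Of 2 further unnamed genes, ENSG00000265150.1 had 0.93 (0.77 to 1.11) from 377 and 1120 reads, and ENSG00000228549 had 0.51 (0.44 to 0.59). For ENSG00000265150.1 the gene type was not known here either, so which RNA it stands for was not determined. Genes with near-identical copies, among them EEF1A1, RPS3P3 and the U2, U4 and 7SK entries, are uncertain, because most alignments in both libraries were not unique and were not counted.

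After SRPRA, the lowest ratios by the same rule belonged to CMTM6, a membrane protein that stabilises PD-L1, at -0.61 (-0.92 to -0.31), and SNX17, an endosomal sorting nexin, at -0.58 (-0.88 to -0.28). The secreted IGFBP2 had -0.52 (-0.78 to -0.26) and the endocytic receptor LRP1, a cargo of SNX17, had -0.50 (-0.80 to -0.21). TIMM8B, BCKDK and CAPN1 lay between -0.50 and -0.49. ZNRD2, MIR191, ANKS1A, SNHG25, BFAR, KLC2, MTX2 and the Golgi glycosyltransferase MGAT5 lay between -0.46 and -0.40.

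Each of 38 gene lists was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. Of 36 lists with at least 3 measured members, 14 lay outside the central 95% of the random lists, 11 low and 3 high. By chance 1.8 would lie outside if the genes of a list varied independently of one another. Genes of a list may vary together between any 2 cultures, and more lists would then lie outside. Ratios were also lower at higher GC content, with a Spearman correlation of -0.28 (Pearson -0.27) across 3958 genes of at least 50 CPM, which are not independent replicates. Median ratios ran from 0.08 in the tenth of genes lowest in GC to -0.05 in the tenth highest. Percentiles among random lists matched on GC as well are therefore given where they alter a list's position. With no matching at all, only 3 lists lay outside, signalling receptors and GPI-anchored proteins low and p53 targets high. Every other list called low or high below, such as ER chaperones at 20.9, then lay within the random range.

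Signalling receptors gave the lowest percentile of all lists. Of 41 measured receptors 34 were lower in the SRα siRNA library, with a median log2 ratio of -0.18 at percentile 0.015, and 3 were at least 1.5-fold lower. The Wnt receptor FZD7 had -0.77 (-1.45 to -0.11), the BMP receptor BMPR1A -0.73 (-2.08 to 0.55), the cytokine receptor subunit IL6ST 0.20 (-0.20 to 0.62) and the TGF-β receptor TGFBR1 0.26 (-0.11 to 0.65). GPI-anchored proteins and the enzymes that make their anchor were lower in 22 of 27 members (median -0.17, percentile 0.025, or within the random range at 4.465 with list means and 4.365 after thinning). EFNA1, an ephrin ligand, had -0.53 (-1.19 to 0.13), NT5E had -0.57 from 4 and 4 reads, the complement regulator CD59 had 0.20 (-0.08 to 0.49), and RTN4R had 0.77 (-0.93 to 2.93).

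Extracellular matrix and secreted proteins were lower in 31 of 41 members (median -0.09, percentile 0.835, or within the random range at 2.98 with GC matched as well and 16.7 after thinning). The secreted growth factor MDK had -0.79 (-1.32 to -0.27), the laminin chain LAMB2 had -0.78 (-1.24 to -0.34), and in the other direction the fibrillin FBN1 had 0.84 (0.17 to 1.57) and the collagen COL5A1 0.36 (-0.52 to 1.30). Solute carriers and ion pumps were lower in 21 of 32 members (median -0.05, percentile 0.795), with the glucose transporter SLC2A3 at -1.89 (-3.86 to -0.43) from 13 and 5 reads, SLC12A4 at -0.57 (-1.43 to 0.27), the calcium pump ATP2B1 at 0.16 (-0.01 to 0.33) and the amino acid transporter SLC1A4 at 0.39 (-0.08 to 0.87). Lysosomal genes were lower in 18 of 30 members (median -0.04, percentile 1.685, or within the random range at 4.63 with GC matched, 5.18 with trends removed and 5.04 with list means). The cholesterol carrier NPC2 had 0.32 (-0.08 to 0.72), SMPD1 -0.23 (-1.09 to 0.63) and the proton pump subunit ATP6V1H -0.21 (-0.45 to 0.03).

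Some lists of the ER's own machinery were low too, and others, given next, were not. The EMC and GET pathways, which insert membrane proteins, were lower in 13 of 16 members (median -0.12, percentile 0.145), with the targeting factor GET3 at -0.30 (-0.60 to -0.01), EMC6 at -0.33 (-1.13 to 0.47), UBL4A at 0.03 (-0.25 to 0.32) and EMC2 at 0.11 (-0.15 to 0.39). Oligosaccharyltransferase and N-glycan assembly genes were lower in 21 of 31 members (median -0.07, percentile 0.135, or 12.8 with list means, within the random range), with the glucosyltransferase ALG10 at -0.65 (-1.14 to -0.17), OST4 at -0.26 (-0.49 to -0.03), the mannose donor enzyme DPM1 at 0.31 (0.11 to 0.52) and ALG9 at 0.83 from 2 and 6 reads. ER chaperones and folding enzymes had a median of -0.04 at percentile 0.815, with 16 of 30 members lower. FKBP2 had -0.25 (-0.51 to 0.00), CRELD1 -0.40 (-1.001 to 0.21), SIL1 0.18 (-0.29 to 0.67) and DNAJB9 0.48 (-0.07 to 1.06). The 5 most-read members, named after their values were seen, were the lectin chaperones CALR at -0.08 (-0.11 to -0.05) and CANX at 0.00 (-0.03 to 0.03), the chaperones HSP90B1 at -0.04 (-0.07 to 0.00) and HSPA5 (BiP) at -0.19 (-0.23 to -0.15), and the disulfide isomerase P4HB at -0.12 (-0.17 to -0.07).

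The other 4 secretory and membrane lists lay within the random range, although some alternative settings placed the translocon, COPII and COPI, and integrin lists below it. The 7 other protein subunits of SRP and its receptor, which are not counted among those lists, had a median of 0.03 (percentile 46.8). Among them SRP72 had 0.17 (0.01 to 0.33), SRP19 had 0.16 from 4 and 7 reads, and SRP9 had -0.21 (-1.26 to 0.85). Translocon and signal peptidase genes had 0.00 (percentile 12.5, with 11 of 22 members lower), with the translocon-associated SSR4 at -0.29 (-0.42 to -0.15), SEC61A2 at -0.37 (-0.79 to 0.05), TRAM2 at 0.16 (-0.61 to 0.97) and SEC62 at 0.17 (-0.02 to 0.38). COPII and COPI transport genes had 0.01 (percentile 18.6), from GOSR2 at -1.27 (-2.81 to 0.04) and TMED7 at -0.38 (-0.91 to 0.14) to SEC13 at 0.23 (0.08 to 0.38) and GOLGA2 at 0.23 (-0.15 to 0.62). Integrins and adhesion receptors had -0.05 (percentile 7.75), with 16 of 26 members lower, from CDH1 at -0.52 (-1.35 to 0.30) and ITGB5 at -0.43 (-0.96 to 0.10) to ITGA6 at 0.27 (-0.02 to 0.56) and ITGA2 at 0.88 (0.27 to 1.53).

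The lists of ATF4 targets, ER-associated degradation, IRE1-dependent decay and heat shock lay within the random range when matched on expression. ATF4 and its targets in the integrated stress response had a median of -0.02 (percentile 5.24), with 16 of 36 members higher and 20 lower. ATF4 itself had -0.27 (-0.47 to -0.08), PCK2 had -0.38 (-0.66 to -0.09), CHAC1 had 0.45 (-1.02 to 2.16) from 6 and 13 reads, and JDP2 had 1.03 from 2 and 7 reads. ER-associated degradation genes had -0.01 (percentile 19.05), with DERL3 at -0.44 (-1.13 to 0.25), AUP1 at -0.28 (-0.60 to 0.04), DERL1 at 0.20 (-0.09 to 0.50) and NPLOC4 at 0.21 (-0.01 to 0.43). Substrates of IRE1-dependent decay would be lower, not higher, if that decay rose. The 5 measured ones had 0.02 (percentile 56.7), with SPARC at -0.60 (-1.17 to -0.05), COL6A1 at -0.35 (-0.58 to -0.12), HGSNAT at 0.18 (-0.43 to 0.80) and SCARA3 at 0.53 (-0.80 to 2.08). Heat shock and cytosolic chaperones had 0.07 (percentile 88.5), with the mitochondrial chaperone HSPD1 at 0.29 (0.21 to 0.38), HSPH1 at 0.23 (0.13 to 0.33), HSPE1 at -0.18 (-0.52 to 0.17) and HSPB1 at -0.25 (-0.70 to 0.20).

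Factors of cap binding and translation initiation were higher in 28 of 40 members (median 0.09, percentile 98.7, or 94.3 after thinning, within the random range), with EIF4B at 0.68 (0.21 to 1.17), EIF3C at 1.26 from 3 and 12 reads, EIF2S3 at -0.14 (-0.24 to -0.03) and EIF4EBP2 at -0.45 (-0.90 to 0.00). Factors of NMD and the exon junction complex were higher in 13 of 19 members (median 0.12), with the kinase SMG1 at 0.29 (0.02 to 0.57), NBAS at 0.28 (0.00 to 0.57), DCP2 at -0.11 (-0.43 to 0.21) and SMG9 at -0.15 (-0.55 to 0.25). Their percentile of 97.53 is barely past the upper limit, and it lay inside the limit in 9 of 14 alternative settings, down to 70.9. Endogenous NMD substrates had 0.06 (percentile 86.2), with 20 of 32 members higher. SNHG1, a snoRNA host gene degraded by NMD, had 0.30 (0.21 to 0.39), GADD45A 0.34 (-0.21 to 0.92), EPB41L4A-AS1 -0.47 (-1.18 to 0.22) and GADD45B -0.57 (-1.40 to 0.23). The p53 targets had 0.15 (percentile 97.95, or within the random range at 96.2 with at least 5 CPM required, 96.2 with list means and 89.4 after thinning), with 15 of 22 members higher. Their extremes had few reads, CDKN1A at 1.37 from 3 and 13, TP53INP1 at 0.70 from 5 and 13, PLK3 at -0.19 from 3 and 4 and BTG2 at -0.87 from 18 and 15.

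Among metabolic lists, fatty acid and phospholipid synthesis was low in 17 of 26 members (median -0.06, percentile 1.395, or within the random range at 23.6 once trends with GC and length were removed and 10.5 with list means). ACSS2 had 0.64 (0.02 to 1.31), CHKA 0.23 (-0.09 to 0.54), GPAT4 -0.31 (-0.70 to 0.08) and LPIN1 -0.35 (-0.97 to 0.28). Glycolysis was low in 11 of 17 members (median -0.04, percentile 1.735, or within the random range in 7 of 14 alternatives, at 11.3 with GC matched), between ALDOC at -0.29 (-0.82 to 0.25) and ENO2 at 0.22 (-0.48 to 0.96), with PFKP at -0.14 (-0.35 to 0.06) and PGAM1 at 0.13 (-0.58 to 0.88). Cholesterol synthesis and uptake lay within the random range (median -0.01, percentile 14.4), with TM7SF2 at -0.75 (-1.67 to 0.14), the regulator SREBF2 at -0.28 (-0.57 to 0.01), ACAT2 at 0.22 (0.07 to 0.37) and MSMO1 at 0.23 (0.03 to 0.45). Nuclear-encoded oxidative phosphorylation had 0.00 (percentile 3.69) and mitochondrially encoded transcripts had 0.06 (percentile 65.1), in which the 12S ribosomal RNA MT-RNR1 had -0.38 (-0.42 to -0.35) and MT-ND6 0.11 (-0.10 to 0.33). Hypoxia-inducible genes had 0.02 (percentile 60.7).

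Among lists of growth and housekeeping, the 13 measured histone genes were low (median -0.04, percentile 1.625, or within the random range at 4.75 with GC matched, 2.995 with length matched and 16.3 after thinning), with the linker histone H1-4 at -0.16 (-0.21 to -0.11) and H2BC21 at 0.11 (-0.03 to 0.25). Cytosolic ribosomal proteins had 0.07 (percentile 93.7, or 98.695 and so high with GC matched), with 53 of 76 members higher, RPL21 at 0.57 (0.05 to 1.11) and RPS27A at -0.51 (-1.01 to -0.01), both of which have many processed copies. The proteasome had -0.01 (percentile 3.36, or 2.145 and so low with GC matched), S-phase genes had 0.05 (percentile 67.9) with the histone mRNA binder SLBP at 0.20 (0.05 to 0.36), and mitotic genes had 0.04 (percentile 49.6), led by TTK. Interferon-stimulated genes had 0.16 (percentile 94.5, 14 of 32 measured) and immediate early genes had -0.09 (percentile 15.4), with JUND at 0.37 (0.02 to 0.73).

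Markers of other cell types showed no list outside the random range. Of 18 hematopoietic markers 2 were measured, among them CORO1A at 0.55 (-0.56 to 1.801), and of 14 hepatocyte markers only APOA1 was, at -0.19 from 3 and 4 reads. Fibroblast markers (6 measured) had a median of -0.17 (percentile 34.3), epithelial markers (4 measured) -0.20 (percentile 19.6) and neuronal markers (5 measured) 0.32 (percentile 92.0). HEK293T cells themselves express some epithelial, mesenchymal and neuronal genes.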

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

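The tests of the secretory and membrane lists and of the counts of 2-fold differences were chosen after the results were seen. Uniquely aligned reads that lie in no gene, which the comparison does not use, made up 7.49% of the SRα siRNA library (exact 95% binomial interval 7.46 to 7.51), above the 7.23% (7.20 to 7.26) of the control siRNA library.

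The pattern most worth a second look is the low position of secretory and membrane lists. All 12 such lists together, whether low or not and with ER-associated degradation among them, held 362 measured genes, and their median differed from matched random lists by -0.10 on the log2 scale, at percentile 0.005, the smallest that 10000 lists can give. The percentile was also 0.005 with GC content matched, 0.005 with length matched and 0.005 once trends with both were removed, with differences of -0.09, -0.10 and -0.09, so neither property accounts for the whole pattern. Their median minus that of all measured genes was -0.08, and 0 of 100 draws of counting error alone gave one as low. A loss of membrane-bound RNA from every organelle would lower mitochondrially encoded transcripts as well. These lay at percentile 65.1, and between 11.2 with list means and 84.7 after thinning. Of 15 measured members 10 were higher, although the ribosomal RNA MT-RNR1 was lower. The list thus shows no such loss but cannot exclude it, since these transcripts may change for other reasons. A loss of membrane-bound RNA during extraction, from the ER alone or more widely, stays open. So do chance differences between 1 culture and another and an effect of SRα depletion, which may lower messages translated at the ER.

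Genes at least 2-fold apart numbered 602 in both directions together, and 6 of 100 draws of counting error alone, drawn apart from the simulated pairs of the comparison itself, gave as many (mean 566, highest 612), so counting error could account for the total. By direction, 80 draws gave at least the 274 higher genes and 0 gave the 328 lower ones, the highest being 314. That split moves with the processing. It was 329 higher and 475 lower after thinning, 252 and 352 with library totals, 186 and 178 with a prior count of 2, and 2872 and 2029 with no filter. The draws were made for 1 setting only. The lower genes exceed counting error in that setting, and the cause was not tested.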

How the results depend on the processing

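Restriction to protein-coding genes, matching on GC and removal of GC and length trends were chosen after seeing the data. SRPRA kept its direction in every alternative, with log2 ratios from -0.86 (thinned to equal totals) to -0.81 (DESeq2 size factors). Counts of genes at least 2-fold apart, 274 higher and 328 lower, followed the filter and the prior. With no filter they were 2872 and 2029, and the standard deviation of log2 ratios was 0.958. With at least 5 CPM required they were 32 and 30, with a standard deviation of 0.282. A prior count of 2 gave 186 and 178, with 0.390. With a 1.5-fold limit they were 835 and 889. The standard deviation was 0.529 after thinning and 0.435 among protein-coding genes. The filters, the larger prior count and the 1.5-fold limit alter the counts by construction, and thinning discards reads and so adds counting error. For the other settings the cause was not tested. Thinning gave 329 higher and 475 lower, totals without mitochondrially encoded and top 10 genes 297 and 353, and the other scalings 252 to 281 and 327 to 352.

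Of 36 lists, 14 lay outside the random range, and 10 to 14 did in the alternatives except that random lists with no matching left 3. With no matching, random lists draw genes of any read depth, and ratios spread more at low depth. The standard deviation was 0.480 over all measured genes and 0.152 over those of at least 50 CPM. Matching on expression also moved the background. Medians of the matched random lists were 0.037 for ER chaperones, 0.035 for lysosomal genes and 0.006 for signalling receptors, against 0.008 over all measured genes. How much of the change the spread or the background makes was not tested. Receptors stayed low in 14 of 14 alternatives, EMC and GET genes, ER chaperones and solute carriers in 13, GPI-anchored proteins and oligosaccharyltransferase in 12, matrix and fatty acid genes in 11, lysosome and histones in 10 and glycolysis in 7. Cap-binding factors stayed high in 12, p53 targets in 11 and NMD factors in 5. No list went from low to high or from high to low. The order of the 2-fold gene counts did turn. Lower genes outnumbered higher ones in the main setting (274 higher, 328 lower). Higher genes were more numerous with a prior count of 2 (186 higher, 178 lower), with no filter (2872 and 2029) and at 5 CPM (32 and 30). Among list percentiles under each alternative, 448 kept their position, 42 came inside the limits and 13 passed them. Those 13 were the translocon (0.245 with trends removed, 1.585 with list means), COPII and COPI transport (0.345 with list means, 1.005 thinned), integrins (1.155 with trends removed), oxidative phosphorylation (0.795 with trends removed, 0.485 with list means), the proteasome (2.145 with GC matched, 1.57 thinned), ATF4 targets (2.34 with at least 5 CPM) and ribosomal proteins (99.755 with trends removed, 98.695 with GC matched, 97.595 thinned). Among named genes and list members only MT-RNR1 moved beyond its interval, to -0.42 with library totals.

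No paired analysis was possible because each group has 1 library, and for that reason no replicate could be left out. Depth limits single genes most. For the median measured gene, with 58 and 88 reads, differences of less than 1.41-fold were within counting error.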

Other observations

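The tests of spliceosomal RNAs in this part were chosen after the result was seen, as were the subclasses of segments and their comparison, and both main tests of hydrophobic segments were chosen before. Reads from RNAs that lack a poly(A) tail were abundant in both libraries, although the labels name an mRNA kit. The U4 RNA gene RNU4-1 had 9056 and 12460 CPM and the Y RNA gene RNY1 had 4695 and 4109 CPM. RNU4-1 was higher in the SRα siRNA library, with a log2 ratio of 0.46 (0.44 to 0.48), and RNY1 was lower, at -0.19 (-0.23 to -0.16). As a class, small nuclear RNAs held 1.51% of gene reads in the control siRNA library and 1.97% in the SRα siRNA library, of which RNU4-1, RNU4-2 and RNU2-59P made up 69.5% and 76.0%.

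The lower level of secretory messages may extend beyond the fixed lists. Among protein-coding genes of at least 5 CPM in no list, 2571 whose protein has a predicted N-terminal or internal hydrophobic segment lay at percentile 0.005 of sets matched on expression and GC, with a median 0.03 below them. The difference was -0.06 for 1018 genes with an N-terminal segment and -0.07 for 519 genes with 4 or more segments, both also at percentile 0.005. It was only -0.01 (percentile 2.18) for 1553 genes with an internal segment. That class lay at 3.07, within the random range, with expression alone matched, at 0.87 with length matched and at 0.16 with trends removed. The 139 genes with a C-terminal segment only had a median of 0.02 at percentile 63.6. This class includes proteins inserted after translation without SRP but is not confined to ER proteins. Equal-sized sets were also drawn from the other classes, without matching on expression or GC. The C-terminal median lay above 99.975% of sets from the N-terminal class, but only 74.9% from the internal class and 29.6% from genes with no segment. Whether the route into the ER matters therefore stays open. The shifts are a few percent in 2 libraries, and loss of ER-bound messages in extraction was not tested on these classes.

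The higher level of small nuclear RNAs rests on 3 entries, named after their values were seen, that have near-identical copies. The summed reads of RNU4-1, RNU4-2 and RNU2-59P had a log2 ratio of 0.54, with a lower counting bound of 0.523. These 3 were picked for their high values, so their bound is no fair check of counting error. Summed reads of all small nuclear RNA genes had 0.42 (0.40 to 0.43), and those without the 3 had 0.07, with a lower bound of 0.038. If reads are independent, counting error alone accounts for neither the summed reads of the class nor those of its remainder. Per gene the class was not clearly higher. The median over 28 small nuclear RNA genes of at least 5 CPM was 0.11, with a 95% bootstrap interval of -0.05 to 0.15. If short noncoding RNA as a whole had been recovered better, small nucleolar RNAs could be higher by as much. Their median over 53 genes was 0.033 (95% bootstrap interval -0.03 to 0.159), and their summed reads had 0.05 (0.00 to 0.10). For the 3 entries these values argue against it. Single short RNAs went both ways, with RNY1 lower and the 7SK entry, from 7 and 32 reads, higher, and so do not decide it. The ratio of the other small nuclear RNA genes lies inside the bootstrap interval of small nucleolar RNAs. For them, recovery of short RNA, chance differences between 1 culture or library and another, and an effect of the siRNA cannot be told apart. For the 3 entries, reads shared between copies, chance differences between 1 culture or library and another, and an effect of the siRNA stay open, all untested.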
